A study of Mus musculus with 12 samples.

How the data were processed

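RNA from mouse cortex was made into directional (strand-preserving) libraries with a NEBNext Ultra II kit, per the labels' protocols. The authors deposited a single table of raw read counts per gene for the 12 libraries, with Entrez gene IDs, exon coordinates and summed exon length. Its columns have the layout that featureCounts writes, per the file headers. The submitters' processing notes name the mm10 build, R 4.1.2 and DESeq2 1.34.0. The aligner, the counter and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart with certainty. Each library's column was matched to its sample by name. The table holds 27179 genes, of which 1049 have no symbol; they stayed in the library totals and the tests. Of the gene IDs, 25275 were found in a RefSeq table of the same assembly, used for names. Reads on mitochondrial genes were few (at most 0.00193% of counts). The mitochondrially encoded list, with 6 of 13 members tested, rests on these reads in every comparison.

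The groups were taken from the labels, which give each library its own age and sex but do not say that each came from a separate animal, so p values measure the spread between these libraries. No 2 libraries agreed within sampling noise, since the lowest chi-square per degree of freedom over the 66 pairs was 3.62. Library totals of 16381221 to 20782195 counts put a gene at the filter's floor of 0.546 CPM near 10 counts. Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15, 4 libraries), which left 15298. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with group means and labelled sex in a single quasi-likelihood model of all 12 libraries, which then share 1 estimate of the spread. The fit had 8 residual degrees of freedom and a common biological coefficient of variation of 0.101. Comparisons were tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05. Age in days was kept out of the model because 3 of the 4 WT animals and no other animal were 375 days old. CPM values use TMM-scaled library sizes.

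The model, the tests, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule names Grn in every library, then, per comparison, up to 8 raised and 8 lowered genes past the threshold with the smallest p whose libraries do not overlap between the groups. It also names up to 4 members past the threshold of each list. Predicted gene models, Y-linked genes and Xist are counted and not named. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way and does not compare them with other genes. Lists with fewer than 5 tested members are not tested, and no list fell under that. A list level is the mean over members of log2 CPM (prior count 2) centred on each gene's mean over the 12 libraries. Fold changes of KO and MUT, which share the WT libraries, were set beside 20 simulated data sets with no effect and beside WT libraries split 2 and 2. Genes within 10 Mb of Grn were compared with all others by Fisher's exact test.

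Alternatives were RLE size factors, library size alone, 2 other low-count filters, DESeq2 1.42.0, limma-voom, other covariates (no sex, age, replicate number as a block), subsets of libraries and each library left out. Where a list is counted over 29 settings, each of them uses the preset correlation. A further 5 alternatives were chosen after seeing the data: the striatal or the choroid plexus list level as a term, leaving out 3 libraries high in choroid plexus genes, removing a trend on gene length and GC content from each library, and an exact permutation test of list levels. The length and GC trend was a spline fit (4 degrees of freedom each), and 97.1% of tested genes had a GC value from GENCODE transcripts, which cover 98.7% of the genes called in KO. The edgeR test was tested on simulated counts of 15298 genes with 200 changed. In the KO design it recovered 30% of genes changed 1.3-fold, 62% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, with 5 false calls among 147. In the MUT against WT design the shares were 54%, 56%, 78% and 96%, with 8 false calls among 150, and in MUT against KO 50%, 74%, 74% and 94%, with 14 among 165. On the same counts, in the order KO against WT, MUT against WT and MUT against KO, DESeq2 made 21 false calls among 170, 29 among 184 and 38 among 202, and limma-voom 5 among 145, 8 among 149 and 15 among 166. With a length trend put into each simulated library and then removed, edgeR made 15 false calls among 159, 8 among 150 and 6 among 161. For a simulated list of 30 raised genes the highest p of the 3 designs was 6.4e-11 with camera, 0.000177 with an estimated correlation, 2.8e-06 with fry and 0.0286 with the exact permutation test, and for 30 unchanged genes the lowest p of these tests was 0.371. Simulated genes varied independently, so correlation within a list was not part of this test. Figures were drawn with matplotlib 3.10.9.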

Results

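RNA was sequenced from mouse cortex in 12 libraries from animals aged 272 to 375 days, in 3 groups of 4 libraries. Wild-type mice (Grn+/+, WT) carried the intact mouse progranulin gene. Knockout mice (Grn-/-, KO) lacked it, and humanized mutant mice (Grn-/- with the allele labelled GRNmEx5, MUT) lacked it in a line built to carry a deletion of human GRN. Progranulin is a secreted glycoprotein that is delivered to lysosomes, and loss of 1 human copy causes frontotemporal dementia. The comparisons ask what loss of mouse Grn changed in the cortex, what the humanized mutant changed, and whether the 2 Grn-null groups differed. Library totals ranged from 16381221 to 20782195 counts, and 15298 genes were tested.

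Grn (Entrez 14824; mm10 chromosome 11, 102430322 to 102436809, plus strand) was lower in every library of both null groups. It measured 58.0 ± 1.35 CPM (counts scaled to the TMM-adjusted library size; mean ± SD, n = 4) in WT, 12.8 ± 1.38 in KO and 13.5 ± 1.59 in MUT. The log2 fold change against WT was -2.20 in KO (SE 0.09, edgeR adjusted p = 4.8e-08) and -2.15 in MUT (SE 0.09, adjusted p = 6.7e-08). Counts summed over the exons of Grn were 21.7% of WT in KO and 22.6% in MUT. MUT and KO were not shown to differ in Grn (log2 fold change 0.06, 95% interval -0.16 to 0.27, adjusted p = 0.993). Human GRN was not analysed here, so the comparison of MUT with KO gives no level of the GRNmEx5 transcript.

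**Figure D1:**
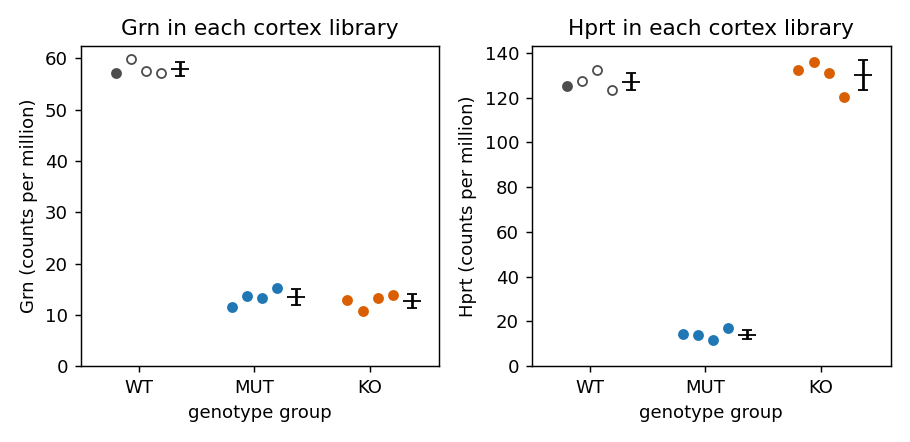
Levels of Grn (left) and Hprt (right) as CPM (y axes) in each of the 12 cortex libraries, by genotype group; points are libraries (open points, animals of 375 days), and bars show the mean ± SD of 4. Grn lies between 57.0 and 59.9 in WT and between 10.8 and 15.3 in both null groups, while Hprt lies between 11.6 and 17.0 in MUT and between 120.3 and 136 in WT and KO.

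The libraries also differed in ways that the genotypes do not name. The first principal component (28.7% of the variance) set WT replicates 2, 3 and 4, all aged 375 days, apart from every other library, including WT replicate 1 of 287 days. Markers of striatal neurons were high in those 3 libraries, with list levels of 0.68, 1.43 and 2.30 on a centred log2 CPM scale, against -0.65 in WT replicate 1 and -0.74 to 0.19 in the 8 null libraries. Ppp1r1b (DARPP-32, a phosphoprotein of striatal projection neurons) measured 155, 253 and 444 CPM in them and 63.3 in WT replicate 1. Penk (preproenkephalin) measured 89.4, 128 and 264 CPM against 14.1. Choroid plexus markers were high in WT replicate 4, MUT replicate 1 and KO replicate 3, with list levels of 1.71, 2.29 and 2.56 against -1.10 to -0.45 in the other libraries. Transthyretin (Ttr), the leading transcript of choroid plexus, measured 598, 1283 and 1839 CPM in those 3 libraries and at most 42.7 in the others. Sex-linked transcripts ran opposite to the sex labels in all 12 libraries. The 6 libraries labelled female held 1 to 19 Xist counts and 1156 to 1654 Ddx3y counts, and the 6 labelled male held 9390 to 12900 Xist counts and 0 to 4 Ddx3y counts. Both codings split the libraries the same way, so the sex term of the model is the same under either. Within WT sex and age coincide, as replicate 1 was the only library labelled female and the only library under 310 days. Results labelled female and results under 310 days thus rest on the same WT library and are not separate checks. Results labelled male leave out WT replicate 1 and hold MUT replicate 3 as the only MUT library.

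Loss of Grn was examined by comparing KO with WT, a comparison that does not isolate Grn. WT replicates 2, 3 and 4 were 375 days old and high in striatal markers, and the KO animals were 282 to 308 days old. Besides Grn, the microglial genes Ctss, Tyrobp and Lyz2 and the complement genes C4b and C1qa rose in KO, and the synaptic genes Gabrb2 and Pclo and the sterol gene Hmgcs1 fell. Ctss (cathepsin S, a lysosomal protease of microglia) rose from 50.8 ± 2.69 to 66.6 ± 4.49 CPM (n = 4 each; log2 fold change 0.39, SE 0.06, edgeR adjusted p = 0.0263). C4b, a complement component, rose from 29.6 ± 5.98 to 56.9 ± 8.56 CPM (0.94, SE 0.16, adjusted p = 0.0397). In all, 75 genes passed an adjusted p of 0.05, 22 higher and 53 lower in KO, and 61 of them changed by less than 1.5-fold.

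Among the other raised genes, Wdfy1, a phosphoinositide-binding adaptor of endosomes, measured 47.9 ± 9.11 CPM in KO and 23.4 ± 1.64 in WT (log2 fold change 0.96, SE 0.13, adjusted p = 0.0247). Fth1, the ferritin heavy chain that stores iron, rose by 0.27 (SE 0.04, adjusted p = 0.0263). Bdh1, a mitochondrial enzyme of ketone body metabolism, rose by 0.24 (SE 0.04), and Acbd4, an acyl-CoA binding protein, rose by 0.39 (SE 0.06), each with an adjusted p of 0.0341. Tbc1d9b, a TBC-domain Rab GTPase-activating protein, rose by 0.26 (SE 0.05, adjusted p = 0.0427). Arhgap27os3 held 45 reads over the 4 KO libraries and 2 over the 4 WT libraries, both in replicate 3. The ratio of pooled reads was 22.2 (95% counting interval 5.81 to 189, without the spread between libraries). The edgeR fit gave a log2 fold change of 4.21 (SE 0.70, adjusted p = 0.0341). Arhgap27os3 lies opposite Arhgap27, so its counts are uncertain where the strand setting of the counting is not known.

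Of the lowered genes, Pappa2, a protease of insulin-like growth factor binding proteins, measured 4.25 ± 1.58 CPM in WT and 0.924 ± 0.393 in KO (log2 fold change -2.01, SE 0.30). St6gal2, a sialyltransferase, fell from 11.9 ± 2.41 to 5.56 ± 0.550 CPM (-1.03, SE 0.14). Lrrc8b, a subunit of volume-regulated anion channels, changed by -0.55 (SE 0.08), and Col19a1, a collagen, by -0.42 (SE 0.06). Slc2a13, the proton-coupled myo-inositol transporter, changed by -0.39 (SE 0.06). Tmem56 changed by -0.35 (SE 0.05) and Pdpk1, the kinase that activates Akt, by -0.31 (SE 0.05). Each of these 7 had an adjusted p of 0.0247. Among libraries labelled female St6gal2 was at -0.49 and Lrrc8b at -0.35, in animals under 310 days Slc2a13 was at -0.25, and none of these 3 values passed.

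**Figure D2:**
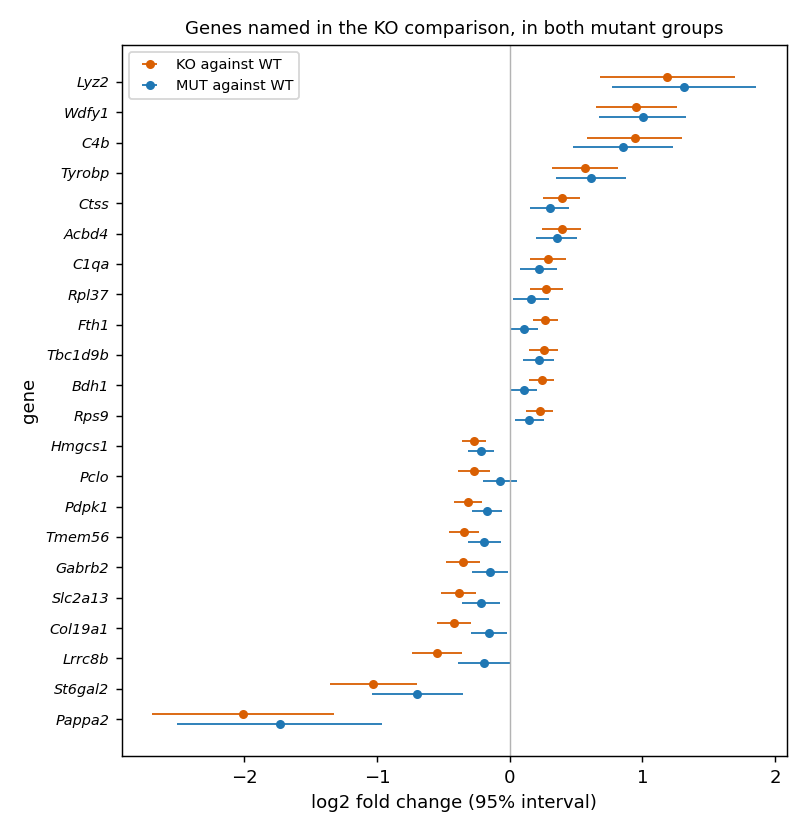
Log2 fold change against WT (x axis, points with 95% intervals) of genes named in the KO comparison (y axis), in KO (orange) and MUT (blue); Grn, Hprt and Arhgap27os3 are left out for scale. Wdfy1, C4b, Lyz2 and Tyrobp lie above 0 in both groups, and Pappa2 and St6gal2 lie below 0 in both.

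The disease-associated microglia list, genes that microglia switch on around damage, was shifted up in KO. Of its 32 tested members, 3 rose past the threshold (10 when adjusted over the list alone) and none fell, with a median log2 fold change of 0.19 (camera adjusted p = 3.3e-07; adjusted p = 0.337 with an estimated correlation). Tyrobp, the adaptor of Trem2, measured 11.2 ± 0.467 CPM in KO and 7.78 ± 1.36 in WT (0.57, SE 0.11, adjusted p = 0.0440). Lyz2, lysozyme of myeloid cells, measured 9.38 ± 1.10 and 4.44 ± 1.63 CPM (1.19, SE 0.22, adjusted p = 0.0440), and Fth1 was the third. With sex and age as terms Lyz2 was at 2.16 and Tyrobp at 0.90, where Tyrobp was not called. With the preset correlation the list was called in 29 of 29 other settings, with medians of 0.16 to 0.33, the highest with sex and age as terms. It was also called by fry (adjusted p = 0.0484), and not by the exact permutation test. The list level lay between -0.06 and 0.21 in the KO libraries and between -0.22 and -0.06 in the WT libraries. Homeostatic microglia genes had a median of -0.02 over 24 members and were not called (adjusted p = 0.969).

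The lysosomal list was called with a smaller median. Of its 59 tested members, 1 rose past the threshold, Ctss (7 adjusted over the list alone), with a median of 0.05 (adjusted p = 3.2e-05; adjusted p = 0.451 with an estimated correlation). The call ended without WT replicate 1 (median 0.024, adjusted p = 0.218) and among libraries labelled male (0.026, adjusted p = 0.205). The median was 0.084 without WT replicate 3. It was 0.13 to 0.20 with the striatal list level or age as a term, among libraries labelled female or in animals under 310 days. Complement genes had 2 of 19 members raised, C4b and C1qa (4 adjusted over the list alone), with a median of 0.16 (adjusted p = 0.00558; adjusted p = 0.451 with an estimated correlation). This call ended without WT replicate 1 (0.12, adjusted p = 0.341) and labelled male (0.15, adjusted p = 0.627). The complement median was 0.079 without KO replicate 1, 0.30 without KO replicate 2, and 0.25 to 0.47 with the striatal level or age as a term, labelled female or under 310 days. The complement level was 0.29 in KO replicate 3, a library high in choroid plexus markers, and -0.14 to -0.015 in the other KO libraries, against -0.33 to 0.0057 in WT. C1qa, the initiating component of the classical pathway, rose from 33.4 ± 2.27 to 40.3 ± 1.90 CPM (0.29, SE 0.06, adjusted p = 0.0499). C4b has a near-identical copy, C4a, and Lyz2, Fth1 and the ribosomal protein genes have paralogs or pseudogenes, so their counts are uncertain where reads map to both.

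The synapse list was shifted down in KO. Of its 38 members, 2 fell past the threshold (11 adjusted over the list alone), with a median of -0.11 (adjusted p = 1.2e-07; adjusted p = 0.451 with an estimated correlation). With a trend on gene length and GC content removed from each library, the synapse median was -0.071 (adjusted p = 7.6e-05). Gabrb2, a GABA-A receptor subunit, fell from 347 ± 30.3 to 268 ± 9.26 CPM (-0.35, SE 0.06, adjusted p = 0.0299), and Pclo, the presynaptic scaffold piccolo, by -0.27 on the log2 scale (SE 0.05, adjusted p = 0.0441). With sex and age as terms Gabrb2 was at -0.17 and was not called. Cholesterol synthesis genes had a median of -0.09, with 1 of 26 members past the threshold (7 adjusted over the list alone; adjusted p = 2.8e-04, and adjusted p = 0.337 with an estimated correlation). That member was Hmgcs1, which makes HMG-CoA for the sterol pathway, at 364 ± 12.4 CPM in WT and 301 ± 7.60 in KO (-0.27, SE 0.04, adjusted p = 0.0247). The cholesterol median was -0.056 with sex and age as terms and -0.059 labelled male, and was called in both.

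The list of the cytosolic ribosome was shifted up in KO, with all 53 members above 0 and a median of 0.17. Rps9 (0.23, SE 0.04, adjusted p = 0.0443) and Rpl37 (0.28, SE 0.05, adjusted p = 0.0484) passed the threshold, and 44 members did when adjusted over the list alone (list adjusted p = 1.2e-26; adjusted p = 0.337 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of 0.08 over 49 members (adjusted p = 1.4e-05; adjusted p = 0.650 with an estimated correlation), none of them past the threshold. Genes raised in KO had a median exonic length of 1296 bases and genes lowered in KO 5828 bases, against 2871 over all tested genes. With the trend on length and GC content removed, 10 genes passed and the ribosomal median was 0.088 (adjusted p = 9.0e-08). The ribosomal median was 0.075 to 0.083 with sex and age as terms, labelled female or under 310 days. The oxidative phosphorylation call ended with the trend removed (0.011, adjusted p = 0.966), and its median was 0.048 labelled female. Rps9 was at 0.13 with the trend removed and Rpl37 at 0.085 with sex and age as terms, and neither was called there.

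Myelin genes had a median of 0.25 over 30 members (4 raised when adjusted over the list alone; adjusted p = 9.5e-11, and adjusted p = 0.451 with an estimated correlation), and 0.41 to 0.46 with the striatal level or age as a term, labelled female or under 310 days. Immediate early genes had a median of 0.18 over 30 members (adjusted p = 0.00980; adjusted p = 0.650 with an estimated correlation). That call ended without WT replicate 1 (0.067, adjusted p = 0.285), without KO replicate 4 (0.15, adjusted p = 0.0889) and labelled male, where the median turned to -0.031 (adjusted p = 0.436). It was 0.30 without KO replicate 2, and 0.27 to 0.43 without the sex term, with age as a term, labelled female or under 310 days. Pericyte and smooth muscle genes had a median of -0.25 over 18 members (adjusted p = 0.00421; adjusted p = 0.738 with an estimated correlation). Their median turned to 0.32 with sex and age as terms, where the list was called as higher (adjusted p = 0.00586), and to 0.22 labelled female, 0.26 under 310 days and 0.052 with the striatal level, where it was not called. The pericyte call also ended without KO replicate 2 (-0.15, adjusted p = 0.0596), and the median was -0.39 without WT replicate 1, -0.17 without WT replicate 3 and -0.41 labelled male. Striatal neuron genes had a median of -1.34 over 19 members (adjusted p = 4.4e-09; adjusted p = 0.451 with an estimated correlation), and hippocampal neuron genes 0.29 over 20 members (adjusted p = 0.0202; adjusted p = 0.650 with an estimated correlation). No member of these 5 lists passed the threshold over all genes by edgeR, and the striatal shift lay in the 3 WT libraries named above. The striatal median was -0.86 without WT replicate 4 and -0.070 with the striatal level, where it was not called. It turned to 0.21 with age as a term, where it was not called, and to 0.36 under 310 days (adjusted p = 0.0168) and 0.38 labelled female (adjusted p = 0.0150), where the list was called as higher in KO. The hippocampal list was called in 19 of 29 other settings, with medians of 0.0091 to 0.44, and not without WT replicate 3 (0.26), WT replicate 4 (0.31) or KO replicate 1 (0.21).

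The other lists were not called in KO. Inhibitory neuron genes had a median of -0.10 (adjusted p = 0.171), with 1 lowered when adjusted over the list alone, and excitatory cortical neuron genes -0.04 (adjusted p = 0.330). Antigen presentation genes had a median of 0.04 (adjusted p = 0.143, with Ctss as the member past the threshold), interferon-stimulated genes 0.08 (adjusted p = 0.230) and reactive astrocyte genes 0.06 (adjusted p = 0.480), with 1 raised when adjusted over the list alone. Endothelial genes had a median of -0.05 (adjusted p = 0.330), oligodendrocyte precursor genes -0.03 (adjusted p = 0.392) and blood cell genes -0.40 (adjusted p = 0.330). Lymphocyte genes had a median of -0.10 (adjusted p = 0.549), border-associated macrophage genes -0.07 (adjusted p = 0.602) and choroid plexus genes -0.15 (adjusted p = 0.634). The choroid plexus level, which carries no sex term, was 0.03 ± 1.70 in KO and -0.04 ± 1.20 in WT. The direction of that list thus depends on the fit. The unfolded protein response list had a median of 0.02 (adjusted p = 0.489), with 2 raised when adjusted over the list alone, as was 1 astrocyte gene. Median, mean and test differed in sign for the astrocyte, meningeal, thalamic and mitochondrially encoded lists, whose medians were -0.01, -0.09, -0.27 and 0.05 and whose adjusted p values were at least 0.966.

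Of the 29 lists, 12 were called with the preset correlation, none of which held with an estimated correlation (camera, 0 lists; 3 at an unadjusted p below 0.05). By fry, which tests whether a list's genes move on balance in the same direction, 3 were called (disease-associated microglia, cholesterol synthesis and ribosomal proteins). Of the genes named by the rule besides Grn, each was called in 8 (C1qa) to 17 (Wdfy1, Pappa2 and St6gal2) of 29 other settings, and Arhgap27os3 in 10 of 26. The count of 75 genes rested on single libraries: it was 1620 without WT replicate 1, 170 without WT replicate 3, and 1 without WT replicate 2, WT replicate 4, MUT replicate 4 or KO replicate 1, 2 without KO replicate 2, 4 without KO replicate 3, 5 without MUT replicate 3 and 11 without MUT replicate 2. It was 2 with age as a further term, 1 with the striatal list level as a term, 2 without the 3 libraries high in choroid plexus genes, 294 without the sex term and 647 by DESeq2.

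**Figure D3:**
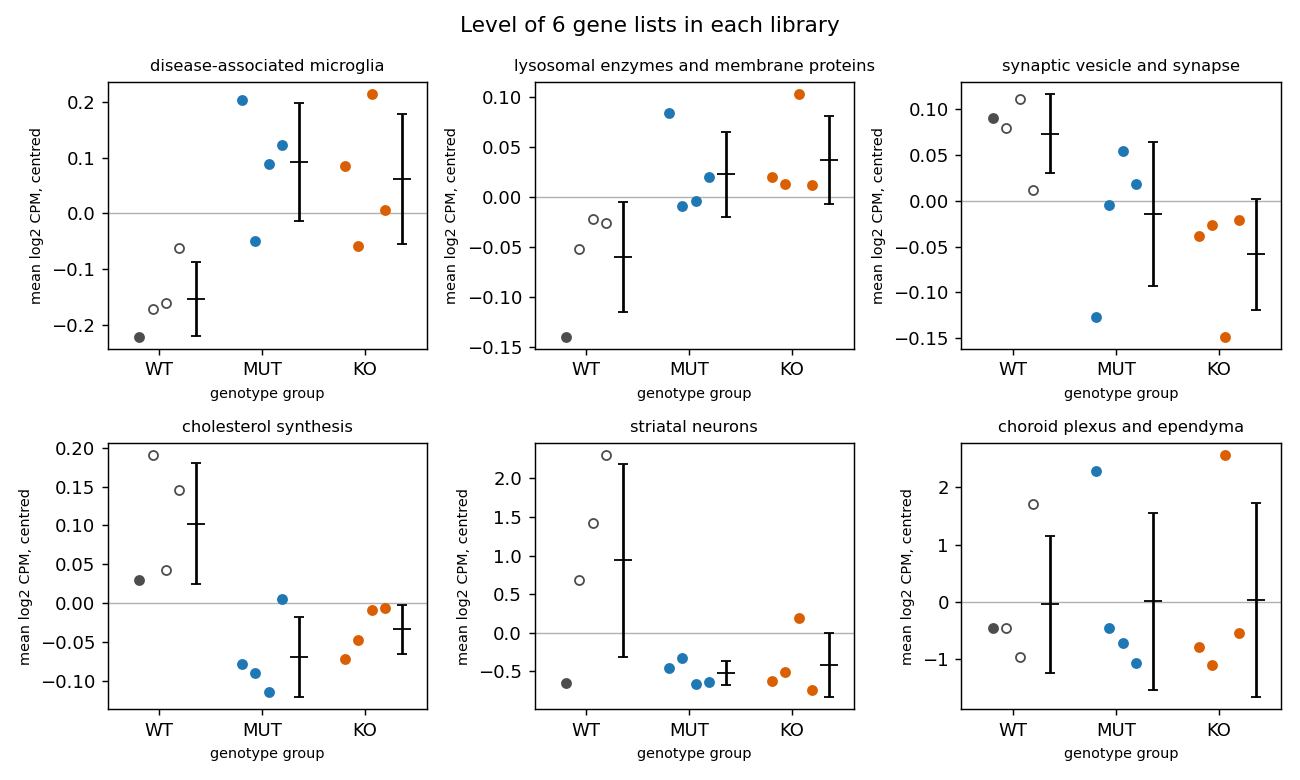
Level of 6 gene lists in each library, as the mean centred log2 CPM of the list's tested members (y axis), by genotype group; points are libraries (open points, animals of 375 days), and bars show the mean ± SD of 4. Disease-associated microglia levels lie between -0.22 and -0.06 in WT and between -0.06 and 0.21 in KO, and striatal levels reach 2.30 in WT.

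The humanized mutant was compared with WT. Beside Grn, 1 further gene passed the threshold, Hprt (Entrez 15452; mm10 chromosome X, 52988078 to 53021660, plus strand), which encodes the purine salvage enzyme hypoxanthine phosphoribosyltransferase. Hprt measured 127 ± 3.91 CPM in WT and 14.2 ± 2.21 in MUT (n = 4 each), a 9.05-fold lower level (log2 fold change -3.18, SE 0.09, edgeR adjusted p = 1.5e-09). It was low in all 4 MUT libraries, with 11.6 to 17.0 CPM. By edgeR 0 genes were raised past the threshold, against 14 by DESeq2 and 1 by limma-voom, and 741 were higher at an unadjusted p below 0.05. Wdfy1 came next, at 52.2 ± 11.5 CPM against 23.4 ± 1.64 (log2 SE 0.14, adjusted p = 0.0722).

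Several lists were called in MUT. The disease-associated microglia list had a median of 0.20 over 32 members (adjusted p = 4.2e-08; adjusted p = 0.270 with an estimated correlation), with 3 raised when adjusted over the list alone. With the preset correlation it was called in 29 of 29 other settings, with medians of 0.17 to 0.36, the highest labelled female. It was not called by fry (adjusted p = 0.0956) or by the exact permutation test. Lyz2 measured 9.60 ± 1.82 CPM against 4.44 ± 1.63 in WT (1.31, SE 0.24, adjusted p = 0.196) and Tyrobp 11.3 ± 0.411 against 7.78 ± 1.36 (0.61, SE 0.11, adjusted p = 0.196). Over 29 other settings Lyz2 ranged from 0.97 to 2.16 and passed in 4, and Tyrobp from 0.46 to 0.90 and passed in 2. Complement genes had a median of 0.26 over 19 members (adjusted p = 4.8e-05; adjusted p = 0.272 with an estimated correlation), with 3 raised when adjusted over the list alone, and C4b measured 53.6 ± 6.50 CPM (0.85, SE 0.16, adjusted p = 0.277). Lysosomal genes had a median of 0.05 over 59 members, 1 raised when adjusted over the list alone (adjusted p = 4.2e-04; adjusted p = 0.475 with an estimated correlation), and Ctss measured 62.6 ± 2.69 CPM (0.30, SE 0.06, adjusted p = 0.277). Without WT replicate 1 the lysosomal median turned to -0.013 (adjusted p = 0.643), and labelled male it was 0.00072 (adjusted p = 0.670). It was 0.032 without MUT replicate 1, 0.030 without the 3 libraries high in choroid plexus genes, 0.076 with library size alone, and 0.096 to 0.16 with the striatal level or age as a term, labelled female or under 310 days. The complement call ended without WT replicate 1 (0.15, adjusted p = 0.224) and labelled male (0.20, adjusted p = 0.114), and its median was 0.39 to 0.59 with the striatal level or age as a term, labelled female or under 310 days. Homeostatic microglia genes had a median of 0.06 and were not called (adjusted p = 0.541).

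Cholesterol synthesis genes had a median of -0.11 in MUT over 26 members, with 4 lowered when adjusted over the list alone (adjusted p = 3.7e-07; adjusted p = 0.221 with an estimated correlation). Hmgcs1 measured 309.7 ± 6.37 CPM against 364 ± 12.4 in WT (-0.22, SE 0.04, adjusted p = 0.229). Synaptic genes had a median of -0.10 (adjusted p = 3.8e-06; adjusted p = 0.393 with an estimated correlation) and excitatory cortical neuron genes -0.10 (adjusted p = 0.0371; adjusted p = 0.393 with an estimated correlation). The synapse call ended labelled male (-0.10, adjusted p = 0.402). The excitatory call ended without WT replicate 1 (-0.13), MUT replicate 1 (-0.074), MUT replicate 2 (-0.10) or KO replicate 4 (-0.089), labelled male (-0.080) and with the length and GC trend removed (-0.10). Ribosomal protein genes had a median of 0.08 (adjusted p = 7.1e-06; adjusted p = 0.519 with an estimated correlation) and the unfolded protein response list 0.13 (adjusted p = 5.7e-05; adjusted p = 0.463 with an estimated correlation). The ribosomal call ended with sex and age as terms (-0.0063), under 310 days (-0.0026) and labelled female (0.0022). Its median was 0.12 without WT replicate 1, 0.049 with the MUT and WT libraries alone and 0.038 with the striatal level. The unfolded protein response call ended with sex and age as terms (0.0070), under 310 days (0.025), with the striatal level (0.035) and labelled male (0.097). Its median was 0.055 labelled female and 0.085 without the 3 libraries high in choroid plexus genes.

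Immune and border-tissue lists were also called as higher in MUT. Antigen presentation genes had a median of 0.30 (adjusted p = 3.8e-04; adjusted p = 0.475 with an estimated correlation) and interferon-stimulated genes 0.24 (adjusted p = 4.3e-04; adjusted p = 0.555 with an estimated correlation). Reactive astrocyte genes had a median of 0.31 (adjusted p = 4.3e-04; adjusted p = 0.393 with an estimated correlation). Border-associated macrophage genes had a median of 0.32 (adjusted p = 0.00438; adjusted p = 0.475 with an estimated correlation) and meningeal genes 0.34 (adjusted p = 0.00233; adjusted p = 0.540 with an estimated correlation). In the antigen presentation, reactive astrocyte and border macrophage lists, 1 member each was raised when adjusted over the list alone. List levels were highest in MUT replicate 1, a library high in choroid plexus markers, for border macrophages (0.73), meninges (1.09) and reactive astrocytes (0.39). The interferon level was 0.53 in MUT replicate 3 and -0.16 to 0.15 in the other MUT libraries.

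None of these 5 calls held without WT replicate 1, where the medians were 0.11 for antigen presentation, 0.12 for interferon-stimulated, 0.31 for reactive astrocyte, 0.20 for border macrophage and 0.14 for meningeal genes (adjusted p = 0.0612 to 0.420). Without MUT replicate 3 the interferon median turned to -0.041 (adjusted p = 0.737), and the antigen presentation, reactive astrocyte and meningeal medians were 0.066, 0.14 and 0.54. Without MUT replicate 1 the border macrophage (0.17) and meningeal (0.068) calls ended (adjusted p = 0.0811 for both), and the antigen presentation median was 0.20, as against 0.19 without the sex term. Labelled male, the border macrophage (0.11) and meningeal (0.022) calls ended, and without KO replicate 3 the interferon median was 0.39. Without the 3 libraries high in choroid plexus genes, the border macrophage and meningeal medians were 0.19 and 0.14. Over all other settings the medians reached 0.57 for interferon, 0.64 for antigen presentation, 0.60 for reactive astrocyte, 0.76 for border macrophage and 0.98 for meningeal genes.

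The myelin, striatal and hippocampal lists were also called between MUT and WT. Myelin genes had a median of 0.12 (adjusted p = 0.00143; adjusted p = 0.671 with an estimated correlation). Their call ended without WT replicate 1 (0.020, adjusted p = 0.663), WT replicate 3 (0.063, adjusted p = 0.0566) or MUT replicate 1 (0.073, adjusted p = 0.0574) and labelled male (0.083, adjusted p = 0.451). The myelin median was 0.21 without WT replicate 4, 0.18 without the 3 libraries high in choroid plexus genes and 0.26 to 0.28 with the striatal level or age as a term, labelled female or under 310 days. Striatal neuron genes had a median of -1.55 (adjusted p = 1.7e-10; adjusted p = 0.393 with an estimated correlation) and hippocampal neuron genes 0.38, with 4 raised when adjusted over the list alone (adjusted p = 2.1e-04; adjusted p = 0.393 with an estimated correlation). The striatal call ended with age (-0.081) or the striatal level (-0.064) as a term, under 310 days (0.043) and labelled female (0.038), and the median was -2.34 without WT replicate 1 and -0.92 without the 3 libraries high in choroid plexus genes. The hippocampal call ended without MUT replicate 3 (0.15, adjusted p = 0.0619), with age as a term (0.15), under 310 days (0.091) and labelled female (0.057), and the median was 0.089 with the striatal level and 0.91 labelled male.

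Lists not called in MUT were astrocytes (median 0.03, adjusted p = 0.199), oligodendrocyte precursors (-0.03, adjusted p = 0.541), pericytes (-0.05, adjusted p = 0.354), inhibitory neurons (-0.02, adjusted p = 0.358) and choroid plexus (-0.62, adjusted p = 0.163). The choroid plexus level, without a sex term, was 0.01 ± 1.54 in MUT and -0.04 ± 1.20 in WT, so its direction depends on the fit. Blood cells (-0.20, adjusted p = 0.334), lymphocytes (-0.24, adjusted p = 0.334), immediate early genes (-0.13, adjusted p = 0.237), oxidative phosphorylation (0.02, adjusted p = 0.372) and mitochondrially encoded genes (-0.16, adjusted p = 0.334) were not called either. The mitochondrially encoded list held 6 tested members with few reads. Endothelial (-0.02, adjusted p = 0.599) and thalamic genes (-0.02, adjusted p = 0.712) had medians opposite in sign to their tests. Of the 29 lists, 16 were called with the preset correlation, 0 with an estimated correlation (3 at an unadjusted p below 0.05) and 1 by fry (cholesterol synthesis). The count of 2 genes became 1030 without WT replicate 1 (and that of lists 9), 311 among libraries labelled male, 52 by DESeq2 and 6 without the sex term.

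The changes of KO and MUT against WT, which share the WT libraries, were set side by side. Across the 15298 genes, which are not independent replicates, the log2 fold changes had a correlation of 0.727 and a covariance of 0.0538. Groups simulated with no effect against shared WT libraries gave a correlation of 0.534 and a covariance of 0.0239. With the WT libraries split 2 and 2 between the comparisons, the covariance was 0.0180 to 0.0324 and the correlation 0.164 to 0.326. Every split left a WT library of 375 days, high in striatal markers, on both sides, so the comparisons still shared that difference. The simulated genes varied independently and held no such structure, so these values do not isolate an effect of Grn. Grn, the gene disrupted in both groups by design, was the only gene lowered past the threshold in both.

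MUT was compared with KO, a comparison that does not isolate the GRNmEx5 allele. Hprt was also low in every MUT library, and human GRN was not analysed here. The cause of a difference between these groups was not tested. Hprt was the only gene past the threshold, at 14.2 ± 2.21 CPM in MUT and 120.3 to 136 CPM in the KO libraries (n = 4 each; log2 fold change -3.21, SE 0.09, edgeR adjusted p = 7.2e-10), and 868 genes had an unadjusted p below 0.05. With the WT libraries left out of the fit, so that they set no part of the shared spread, 39 genes passed between MUT and KO. Hprt did not pass between KO and WT (0.03, SE 0.08, adjusted p = 0.894). The disease-associated microglia, lysosomal and complement lists were not called between the null groups, with medians of -0.0033, -0.02 and 0.05 and adjusted p values of 0.964, 0.277 and 0.277. The mean of the disease-associated list was 0.03, opposite in sign to its median.

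Other lists differed between MUT and KO with the preset correlation. Immediate early genes had a median of -0.28 over 30 members (adjusted p = 1.9e-08) and ribosomal protein genes -0.11 over 53, with 4 lowered when adjusted over the list alone (adjusted p = 1.0e-18); each had an adjusted p of 0.428 with an estimated correlation. With the length and GC trend removed the ribosomal median was -0.035 (adjusted p = 0.00131), and labelled female it was -0.070. The immediate early median was -0.17 without MUT replicate 1, -0.45 without MUT replicate 4, -0.15 labelled male and -0.18 without the 3 libraries high in choroid plexus genes. Border-associated macrophage genes had a median of 0.40, with 10 of 10 members above 0 and 2 raised when adjusted over the list alone (adjusted p = 2.9e-06; adjusted p = 0.428 with an estimated correlation). Their median was 0.18 without MUT replicate 1, 0.69 without KO replicate 3, 0.23 under 310 days, 0.24 without the 3 libraries and 0.21 labelled male, where the call ended (adjusted p = 0.152). Myelin genes had a median of -0.13 and oxidative phosphorylation genes -0.05 (adjusted p = 7.9e-07 for both; adjusted p = 0.710 with an estimated correlation). The myelin call ended without KO replicate 3 (-0.070, adjusted p = 0.0792) and labelled male (-0.079). The oxidative phosphorylation call ended with the length and GC trend removed (-0.0051, adjusted p = 0.637) and labelled female (-0.013), and the median was -0.026 without MUT replicate 3, -0.085 without KO replicate 4 and -0.13 labelled male.

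Further lists were called as higher in MUT than in KO, each of them lost when 1 library or another was left out. The lists of meninges (0.41, adjusted p = 2.5e-04), pericytes (0.21, adjusted p = 0.00433), endothelial cells (0.12, adjusted p = 0.0261), reactive astrocytes (0.15, adjusted p = 0.00198), interferon-stimulated genes (0.09, adjusted p = 0.0237), antigen presentation (0.16, adjusted p = 0.0336) and the unfolded protein response (0.10, adjusted p = 7.0e-05) made up this group. Each of these 7 had an adjusted p of 0.710 or, for interferon-stimulated genes, 0.792 with an estimated correlation. Without MUT replicate 1 the calls ended for meninges (0.10, adjusted p = 0.138), pericytes (0.0078, adjusted p = 0.555), endothelial cells (0.029, adjusted p = 0.815), reactive astrocytes (0.084, adjusted p = 0.0707) and antigen presentation (0.016, adjusted p = 0.442). The unfolded protein response call ended without KO replicate 3 (0.024, adjusted p = 0.425), without the 3 libraries high in choroid plexus genes (0.029) and labelled male, where it turned (-0.033), and the median was 0.15 without MUT replicate 3 and 0.18 labelled female. The meningeal call also ended labelled male (0.20), and its median was 0.23 without the 3 libraries. The reactive astrocyte call also ended without MUT replicate 3 (0.11) and labelled female (0.044), and its median was 0.23 without MUT replicate 2, 0.31 without KO replicate 3, 0.095 without KO replicate 4 and 0.27 labelled male.

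The other 4 of these lists were called in fewer settings. The interferon list was called as higher in MUT in 18 of 29 other settings, with medians of up to 0.71 (labelled male), and as lower in MUT in 1, labelled female (-0.20, adjusted p = 2.4e-05). Its median turned without MUT replicate 3 (-0.079) or KO replicate 2 (-0.018), its call ended without WT replicate 1 (0.11), WT replicate 3 (0.086), MUT replicate 1 (0.10) or KO replicate 1 (0.036), and it was 0.14, 0.21 and 0.36 without MUT replicate 2, MUT replicate 4 and KO replicate 3. The antigen presentation list was called in 15 of 29, with medians of -0.043 labelled female to 0.31 without KO replicate 3. Its call also ended without WT replicate 1 (0.13), WT replicate 3 (0.16), WT replicate 4 (0.16), MUT replicate 3 (0.066), KO replicate 1 (0.090), KO replicate 2 (0.12) or KO replicate 4 (0.18). The endothelial list was called in 19 of 29, with medians of 0.014 labelled female to 0.14. Its call also ended without WT replicate 1 (0.072), WT replicate 3 (0.11), KO replicate 1 (0.056), KO replicate 2 (0.072) or KO replicate 4 (0.055). The pericyte list was called in 21 of 29, with medians of 0.0078 to 0.31. Its call also ended without WT replicate 1 (0.12) or KO replicate 2 (0.15), and its median was 0.12 without KO replicate 4.

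The remaining lists were not called between MUT and KO. Synaptic genes had a median of 0.01 with 3 raised when adjusted over the list alone (adjusted p = 0.276), cholesterol synthesis -0.04 (adjusted p = 0.244), homeostatic microglia 0.01 (adjusted p = 0.409) and astrocytes 0.04 (adjusted p = 0.0759). Excitatory neurons had a median of -0.06 (adjusted p = 0.297), inhibitory neurons 0.05 (adjusted p = 0.372), striatal neurons -0.05 (adjusted p = 0.841), hippocampal neurons 0.06 (adjusted p = 0.277) and thalamic neurons 0.11, with 1 raised when adjusted over the list alone (adjusted p = 0.744). Oligodendrocyte precursors had a median of -0.01 with a mean of the opposite sign (adjusted p = 0.560). Choroid plexus (-0.31, adjusted p = 0.277), blood cells (0.11, adjusted p = 0.744), lymphocytes (-0.11, adjusted p = 0.744) and mitochondrially encoded genes (-0.13, adjusted p = 0.292) were not called. Of the 29 lists, 12 were called with the preset correlation and 0 with an estimated correlation or by fry, against 3 and 2 at an unadjusted p below 0.05. The single gene became 18 without WT replicate 3, 5 without WT replicate 1, 2 without KO replicate 2, 15 by DESeq2 and 39 with the WT libraries left out.

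Genes near Grn were examined because a targeted locus can carry flanking DNA of the stem cell strain. In KO, 3 of 287 tested genes within 10 Mb of Grn passed the threshold, Adam11, Acbd4 and Arhgap27os3, against 71 of 15010 elsewhere (two-sided Fisher's exact p = 0.162). Adam11, a catalytically inactive member of the ADAM family expressed in neurons, was outside the naming rule and chosen after its values were seen. It measured 302 ± 11.7 CPM in KO and 219 ± 25.9 in WT (0.46, SE 0.08, adjusted p = 0.0440). In MUT, 0 of 287 genes near Grn passed by edgeR, against 5 by DESeq2 and 49 at an unadjusted p below 0.05. The KO count was 39 without WT replicate 1 and 0 without WT replicate 2 or 4, KO replicate 1, 2 or 3, or MUT replicate 2, 3 or 4, and the MUT count was 30 without WT replicate 1.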

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

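The length and GC correction, the tests of striatal tissue, of age and of the share of microglia, and those of unadjusted p values around Grn were chosen after the data were seen, whereas the counts past the adjusted threshold within 10 Mb of Grn were planned. Of 174 groups of 4 values, 15 had a highest or lowest library whose gap to the nearest of the others exceeded 0.829 of the group's range. Chance gives about 5% of groups.

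In WT, the gap was 1 for Arhgap27os3 in replicate 3, which held the only WT reads, 0.834 for Slc2a13 (lowest in replicate 1), 0.946 for Rpl37 and 0.944 for the ribosomal protein level (both highest in replicate 1) and 0.899 for the second principal component (highest in replicate 4). In MUT it was 0.831 for Tyrobp (lowest in replicate 2) and, each highest in replicate 1, 0.862 for Rps9, 0.865 for the endothelial level, 0.919 for the pericyte level and 0.961 for the border macrophage level. In KO, replicate 3 was highest for Wdfy1 (0.910; 61.5 against 42.6 to 44.3 CPM), the lysosomal level (0.905) and the choroid plexus level (0.850), and lowest for the synapse level (0.863) and the unfolded protein response level (0.967).

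Other splits of the 8 libraries do not exclude chance for the count of genes between KO and WT or for any count of lists. As many as the 75 genes between KO and WT came from 2 of 35 splits (highest other 215), and as many as its 12 lists from 9 (highest other 19). As many as the 16 lists between MUT and WT came from 9 splits (highest other 20), and as many as the 12 between MUT and KO from 18 (highest other 21). For the 2 genes between MUT and WT (3 splits with as many, highest other 486) and the 1 between MUT and KO (2 splits, highest other 1), a count carries nothing of the size of a change and decides nothing on Grn and Hprt. Their groups did not overlap, and both stayed past the threshold in 29 of 29 settings. The splits with 215 and 486 genes placed WT replicate 1 with the null libraries low in choroid plexus markers and the other 3 WT libraries with KO replicate 3 or MUT replicate 1, which points to a structure of the samples other than genotype.

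The genes that differed between KO and WT were short where higher and long where lower. Over the 74 genes besides Grn, removing a length and GC trend from each library left a median 0.808 of the log2 fold change (quartiles 0.708 to 0.944). These genes were picked by passing the fit with the trend left in, which favours a high ratio. The ratio therefore does not decide on the trend as the whole cause. Over all tested genes, log2 fold change had a Spearman correlation with exonic length of -0.27 in KO against WT. It was -0.10 in MUT against WT and 0.26 in MUT against KO. After removal of the trend 9 of the 74 genes stayed past the threshold. Their median absolute log2 fold change, over all 74, went from 0.37 to 0.29 at SE 0.06 both times. Why the other calls ended was not tested. With the striatal level as a term the median ratio was 0.913 (quartiles 0.791 to 1.05), or 1.22 without the WT library of 287 days. The striatal list went from -1.34 to -0.070. These genes were picked by passing the fit without that term, and 74 of the 75 called genes did not overlap between the groups. Genes that follow the striatal level vary widely within WT and were unlikely to be picked (0 of 19 striatal markers passed). The ratio therefore does not decide on striatal tissue. With the striatal term 0 of the 74 passed by edgeR, and 74 had an unadjusted p below 0.05. The median absolute log2 fold change went from 0.37 to 0.32 and the SE from 0.06 to 0.08, and why the calls ended was not tested. Against the WT library of 287 days alone the ratio was 0.748 (quartiles 0.593 to 1.03), which rests on 1 library, so age cannot be told apart from genotype. The length and GC trend, age, striatal tissue and genotype all stay open.

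The disease-associated microglia list was called as higher in both null groups with camera's preset correlation, and not with an estimated correlation (adjusted p = 0.337 in KO and 0.270 in MUT). In the main fit the higher median of the homeostatic list was 0.0646 (95% interval over genes -0.05 to 0.12 in MUT). This lay below the disease-associated median in both groups. An interval over genes does not measure the spread between libraries, so it does not decide on a larger share of microglia of any state. The homeostatic interval lay above 0 in both groups with the striatal level as a term (0.08 in KO, 0.12 in MUT) and with sex and age (0.19 and 0.20). A larger share thus stays open. It reached 0 in both with the striatal level but without the WT library of 287 days (0.02 and 0.08). More microglia in a changed state are not addressed by this list. With the striatal level as a term, the disease-associated median was 0.270 in KO (95% interval over genes 0.09 to 0.42). In MUT it was 0.30 (0.12 to 0.48). Within WT, replicates 1 to 4 had disease-associated levels of -0.22, -0.17, -0.16 and -0.06 at striatal levels of -0.65, 0.68, 1.43 and 2.30. The fit does not decide on striatal tissue. Without the WT library of 287 days, where the medians were 0.31 and 0.28, it reaches beyond the striatal range of the WT libraries. With all libraries it leans on that library, the only WT library in the striatal range of the null libraries. Against that library alone the lower of the KO and MUT medians was 0.305 (0.11 to 0.51), with homeostatic medians of 0.15 and 0.17, but with 1 WT library age cannot be told apart from genotype. Genotype stays open too, and no test of microglial state was made.

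Hprt was low in MUT alone, and genes within 5 Mb of Grn held more low unadjusted p values against WT than genes elsewhere, although within 10 Mb 3 of 287 in KO and 0 of 287 in MUT (49 with an unadjusted p below 0.05) passed the adjusted threshold by edgeR. A change of the whole region around Hprt is argued against, since 42 tested genes within 5 Mb had a median of -0.0327 between MUT and KO (95% interval -0.06 to 0.03). Within 5 Mb of Grn, 24 of 202 genes in KO (11.9%, against 6.70% elsewhere; two-sided Fisher's exact p = 0.00681) and 19 of 202 in MUT (9.41%, against 2.38%; exact p = 6.5e-07) had an unadjusted p below 0.01, and 3 of 202 between MUT and KO; as large a share occurred in 4.92% of other windows for KO and in 0% for MUT. Within 10 Mb it was 27 of 287 in KO (9.41%, against 6.72%; exact p = 0.0754) and 20 of 287 in MUT (6.97%, against 2.39%; exact p = 3.2e-05). This is consistent with flanking DNA of another strain, although the excess in KO depended on the window, windows overlap, and the deletion itself stays open.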

How the results depend on the processing

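The terms for striatal and choroid plexus level, the set without 3 libraries, the length and GC trend and the exact test were chosen after seeing the data. Grn against WT, and Hprt in MUT against both groups, stayed past the threshold with the same direction in 29 of 29 settings. Leaving out single libraries gave Grn -2.25 to -2.12 in KO and -2.21 to -2.08 in MUT, and Hprt -3.26 to -3.04 against WT and -3.29 to -3.08 against KO. Of the other results on named genes, 962 kept direction and side of the threshold, 360 lost the call, 35 gained it and 1 reversed. The 962 include genes that were not called to begin with, as were all of these genes in MUT against WT, so they do not measure how calls held. Genes named by the rule in KO besides Grn stayed past the threshold in 8 (C1qa) to 17 (Wdfy1) of 29 other settings, and Arhgap27os3 in 10 of 26. For every result below that moved, the cause was not tested.

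Genes past the threshold in KO numbered 647 by DESeq2, 294 without the sex term, 2 with sex and age, 2 with the replicate block, 3 with only the 2 groups, 2 in libraries labelled female, 1163 in those labelled male, 11 in animals under 310 days, 1 with the striatal level, 301 with the choroid plexus level, 2 without the 3 libraries high in choroid plexus genes, 509 at an adjusted p of 0.1, 10 with the length and GC trend removed, and 1 to 1620 leaving out each library. MUT against WT gave 52 by DESeq2, 6 without sex, 311 labelled male, 4 at 0.1, 3 with sex and age, under 310 days or without the 3 libraries, 3 by limma-voom, and 2 to 1030 leaving out each library (1030 without WT replicate 1). MUT against KO gave 15 by DESeq2, 2 with sex and age, 39 with the 2 groups, 2 labelled male, 37 under 310 days, and 1 to 18 leaving out each library. Genes near Grn in KO were 17 by DESeq2, 12 without sex, 0 with sex and age, the block, the 2 groups, labelled female, the striatal level or without the 3 libraries, 23 labelled male, 1 under 310 days, 11 with the choroid plexus level, 16 at 0.1, 1 with the trend removed, and 0 to 39 leaving out each library. In MUT they were 5 by DESeq2, 1 by limma-voom, without sex, under 310 days and at 0.1, 6 labelled male, and 0 to 30.

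Lists called in KO were 22 with sex and age, 20 labelled female, 0 with an estimated correlation, 3 by fry, 0 by the exact test and 9 to 15 leaving out each library; in MUT 0, 1 and 0 by those tests and 9 to 18; in MUT against KO 0, 0 and 0, and 8 to 13. With WT libraries split, the covariance was 0.0191, 0.0180, 0.0292, 0.0324, 0.0306 and 0.0293.

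Reversed results were as follows. With sex and age, in KO, the medians were 0.32 for pericytes, 0.21 for striatal and 0.11 for hippocampal genes, the last reversed by its test, and -0.0063 for ribosomal genes in MUT. Labelled female, they were 0.22 for pericytes and 0.38 for striatal genes in KO, 0.038 for striatal and 0.0022 for ribosomal genes in MUT (the latter reversed by its test), and -0.20 for interferon-stimulated and -0.043 for antigen presentation genes in MUT against KO, with Grn at -0.021 there. Under 310 days, they were 0.26, 0.36 and 0.056 for pericyte, striatal and hippocampal genes in KO (the last reversed by its test), and 0.043 for striatal and -0.0026 for ribosomal genes in MUT. Labelled male, they were -0.080 for excitatory neuron genes in MUT, by its test, and -0.033 for the unfolded protein response in MUT against KO. Without MUT replicate 3, interferon-stimulated genes were at -0.041 against WT (highest 0.39 leaving out each library) and -0.079 against KO (highest 0.36); without KO replicate 2, Grn was at -0.00019 in MUT against KO and Hprt at -0.011 in KO (highest 0.064). Without WT replicate 1 the median of lysosomal genes in MUT turned to -0.013, though not its test. Labelled male, that of immediate early genes in KO was -0.031, and without KO replicate 2 that of interferon-stimulated genes in MUT against KO was -0.018. Grn in MUT against KO ranged from -0.00019 to 0.13 leaving out each library, and from -0.021 to 0.16 over all 29 settings.

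Same-numbered libraries did not pair (correlations -0.377 to 0.289; 2 of 12 best with their own number). The replicate block gave 2, 2 and 1 genes and 12, 16 and 12 lists. Depth limits genes near 0.546 CPM, the floor of the filter.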

Other observations

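Gfap, the intermediate filament of astrocytes, was outside the naming rule and chosen after its values were seen. It measured 105.2 ± 36.1 CPM in WT, 231 ± 37.0 in KO and 256 ± 35.9 in MUT (n = 4 each). The log2 fold change was 1.11 in KO (SE 0.22, edgeR adjusted p = 0.0655) and 1.23 in MUT (SE 0.23, adjusted p = 0.277), so neither passed the threshold. All 8 null libraries lay above all 4 WT libraries. The highest WT value, 154 CPM, was in replicate 1, the WT library of 287 days and low in striatal markers, and the 3 WT libraries of 375 days ranged from 74.8 to 110.0 CPM. Gfap lies on chromosome 11 within 5 Mb of Grn.

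An exact permutation test of list levels, chosen after seeing the data, cannot go below p = 0.0286 with 4 libraries against 4. The levels of the lysosomal, disease-associated microglia, synapse, cholesterol synthesis and ribosomal protein lists did not overlap between KO and WT (two-sided exact p = 0.0286 each, adjusted p = 0.166 over 29 lists). Those of the lysosomal, disease-associated microglia, cholesterol synthesis and unfolded protein response lists did not overlap between MUT and WT (exact p = 0.0286, adjusted p = 0.207). Border macrophage and ribosomal protein levels did not overlap between MUT and KO (exact p = 0.0286, adjusted p = 0.414).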
